A study of Caenorhabditis elegans with 6 samples.

How the data were processed

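The series holds ChIP-seq libraries from C. elegans raised at 20 °C and fed empty vector or a mixture with 50% cco-1 RNAi from the egg to the late larval or young adult stage, per the labels' protocols. Worms were fixed with 1% formaldehyde for 30 min. There are 6 libraries in 6 groups with 1 library per group. The numbers in the sample titles go with the antibody and were not read as replicates.

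The deposited tables, 1 per mark, give for each peak a position, the nearest gene by WormBase identifier and symbol, and a whole-number count for empty vector and for cco-1 RNAi, per the file headers. The values were read as counts because they are whole numbers with different totals per library, although rounding of a normalized unit by the authors cannot be excluded from the values. The submitters' processing notes name FastQC, Bowtie2 2.3.5, SAMtools 1.4.1 and MACS2 2.1.2 and the builds WBcel235 and ce11, without roles. Which program counted the reads, how reads were filtered, whether peaks were called on pooled libraries and how the inputs were used are not given in the sources used here. Both conditions of a mark share 1 peak set. How peaks were called decides which regions can be seen at all, and counts are not corrected for input.

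The tables held 17331 and 17877 lines for H3K18ac and H3K27ac. Of these, 119 and 111 repeated a peak that has several nearest features and were counted once in totals. Mitochondrial peaks (5 and 3) had 0 counts in both conditions and were left out. This left 17207 and 17763 nuclear peaks, all with counts above 0 (minimum 5 for H3K18ac and 18 for H3K27ac). The depth per library, as counts in peaks, was 8293828 and 8948860 for H3K18ac and 11556404 and 11593321 for H3K27ac, for empty vector and cco-1 RNAi. At the median count, counting error alone gives a ratio a relative error of 8.34% for H3K18ac and 7.71% for H3K27ac. The chromosome X lines end at 7889771 and 12935256 bp.

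Counts were divided by the library's total in nuclear peaks and expressed per 1000000 (CPM). The log2 ratio of cco-1 RNAi over empty vector was taken per peak without a pseudocount. Exact (Clopper-Pearson) 95% intervals of the fold were computed from the 2 counts and cover counting error only. Genes took the assigned peak with the larger mean CPM. A peak or gene was described as risen or fallen when the ratio was at least 1.5-fold. No test was made between conditions, because no group has replicates.

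The plan fixed before the data were examined assumed values normalized by the authors, with a pseudocount at the 5th percentile of the values. Because the tables hold counts, scaling to CPM was used, and because no nuclear peak had a count of 0 the pseudocount was dropped from the leading values. Both decisions were made after the tables had been looked at. Results with the planned pseudocount (7.60 CPM for H3K18ac and 7.01 CPM for H3K27ac) and without scaling are reported as alternatives.

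Named genes follow a rule fixed before the data were examined: cco-1, hsp-6, hsp-60, atfs-1, dve-1 and cbp-1 always; for each mark the 10 largest rises and the 10 largest falls among genes whose mean CPM is at or above the median of peaks; and up to 4 members of each list with the largest absolute log2 ratio under the same floor. The genes that moved in opposite directions in the 2 marks were named after their values were seen. The 14 gene lists, fixed at the same time, were UPRmt effectors (mitochondrial chaperones, proteases and import, with other genes induced by the response); UPRmt transcription and chromatin regulators; oxidative phosphorylation; mitochondrial ribosome; tricarboxylic acid cycle; glycolysis and gluconeogenesis; cytosolic heat shock; endoplasmic reticulum unfolded protein response; oxidative stress and detoxification; innate immunity; autophagy and lysosome; cytosolic ribosome; cuticle collagens; and histones. The 7 marker lists were germline and oocyte, sperm, intestine, body wall muscle, pharynx, neuron and hypodermis. The ribosome, collagen and histone lists were taken by symbol, so the histone list includes members outside the replication-dependent clusters. The median of a list with at least 5 measured genes was given as a percentile among 10000 random lists of the same size matched on deciles of mean CPM, as a description of these libraries.

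Gene positions come from the deposited tables. A RefSeq gene table of the same build matched 91.9% and 91.7% of the assigned genes by symbol. Among matched genes 62.7% and 63.9% were protein coding, 21.8% and 21.5% non-coding RNA genes and 5.93% and 5.04% piRNA loci, so a nearest feature is not always the gene a peak regulates. The table holds no exons, so peaks were placed only as near a start, in a gene body or between genes.

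The alternatives were a 2-fold threshold, median scaling, peaks of at least median strength, the pseudocounts, the peak nearest to the gene start and peaks within 1 kb of it, matching of the marks by overlapping peaks, and promoters within 500 bp. Unscaled counts, TMM scaling with edgeR 4.0.16 and lowess centring on peak strength (fraction 0.3) were added after the data had been seen, as were the oxidative phosphorylation list without cco-1 and the UPRmt effector list cut to chaperone, protease and import genes, and the matching of histone genes by overlapping peaks. A stricter peak threshold was planned and not run, because the tables hold no peak score. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

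The calculation was tested on simulated data: Poisson counts for the 17207 H3K18ac and 17763 H3K27ac peaks, with 200 peaks changed 2-fold up or down in each. Of peaks raised 2-fold, 100% (H3K18ac) and 99% (H3K27ac) passed 1.5-fold, and of peaks lowered 2-fold 99% and 100%. Of the unchanged peaks 0.318% and 0.125% passed. The intervals held the true fold for 95.4% of peaks for each mark, and 7 and 4 of 100 random lists without a change lay outside the central 95%. The simulation held counting error only. These rates therefore do not tell how many unchanged peaks pass 1.5-fold through variation between worm samples or precipitations.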

Results

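Histone acetylation was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in the nematode Caenorhabditis elegans, strain N2 per the sample labels. The series design adds that the worms carried a green fluorescent reporter of hsp-6, a gene of the mitochondrial unfolded protein response (UPRmt), which the sample labels do not state. Worms were fed bacteria with an empty RNAi vector, or a mixture in which 50% of the bacteria carried RNAi against cco-1, a nuclear-encoded subunit of cytochrome c oxidase whose loss stresses mitochondria. Chromatin was precipitated with antibodies against acetylated lysine 18 (H3K18ac) or lysine 27 (H3K27ac) of histone H3, both of which are acetylated by enzymes of the CREB-binding protein family. The labels gave 6 libraries in 6 groups, 1 per group: each mark in each RNAi condition, and an input for each condition. The input libraries were not analysed here. The tables gave counts per peak that summed to 8293828 (empty vector) and 8948860 (cco-1 RNAi) for H3K18ac, and to 11556404 and 11593321 for H3K27ac; values are compared as counts per 1000000 counts in peaks (CPM). Because each group had 1 library, no difference described here has a replicate check and no p-value is given, and the 95% intervals on fold changes cover counting error only.

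The H3K18ac table held 17207 peaks assigned by the authors to 11891 genes, and the H3K27ac table held 17763 peaks assigned to 12551 genes (build ce11). The median peak width was 520 bp for H3K18ac and 489 bp for H3K27ac. Within 1 kb of the start of the assigned gene lay 62.3% of the H3K18ac peaks (exact binomial 95% interval 61.6 to 63.1%) and 62.6% of the H3K27ac peaks (61.9 to 63.3%). A further 13.1% and 13.8% overlapped the body of the assigned gene, and 24.6% and 23.6% lay between genes, while exons and introns were not told apart here. On chromosome X the tables reached 7.89 Mb for H3K18ac and 12.9 Mb for H3K27ac, and the rest of X was not analysed here. In the part of the genome covered by both tables, 84.8% of H3K18ac peaks overlapped an H3K27ac peak by at least 1 bp, and 85.8% of H3K27ac peaks overlapped an H3K18ac peak.

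The comparison of cco-1 RNAi with empty vector asked where H3K18ac changed under mitochondrial stress. The RNAi target itself had the largest rise of all H3K18ac peaks: the peak covering cco-1 (WBGene00000371, chromosome I, 9787746 to 9789970) went from 3111 to 27918 counts, 8.32-fold in CPM (95% interval 8.01 to 8.63). The counts are of precipitated DNA, so they do not measure the transcript of cco-1, and DNA of the feeding plasmid with a copy of the target was not separated from the worm gene. H3K18ac rose at hsp-60, the mitochondrial chaperonin, by 1.87-fold (1.80 to 1.94, chromosome III, 1618143 to 1620502, over the gene start). At hsp-6, the mitochondrial Hsp70-type chaperone, the stronger peak, over the gene start (chromosome V, 4826391 to 4828370), had a fold of 0.96 (0.91 to 1.02), while a weaker peak inside the gene (4825205 to 4825899) rose from 351 to 705 counts, 1.86-fold (1.64 to 2.12). A further weak peak over the gene (4824496 to 4824807), assigned by the authors to adss-1, rose from 100 to 172 counts, 1.59-fold (1.24 to 2.06). Whether a reporter with the hsp-6 promoter added reads here is unknown, and none were separated from those of the worm gene.

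**Figure D1:**
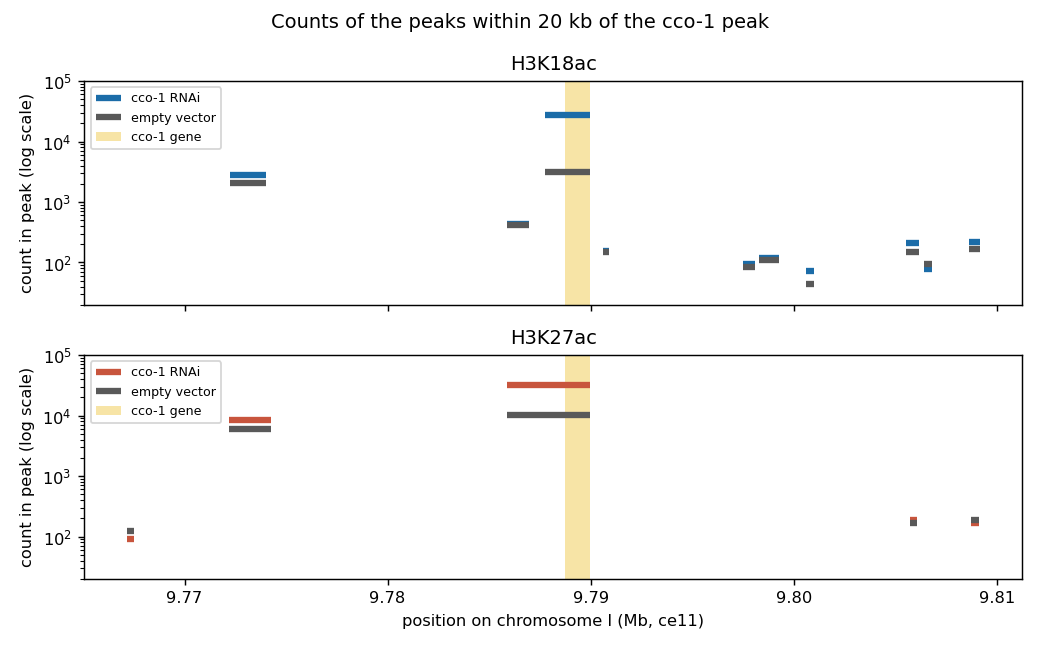
Counts (log scale) of each peak within 20 kb of the cco-1 peak against position on chromosome I (Mb), with grey bars for empty vector, coloured bars for cco-1 RNAi and a shaded band for the gene. The peak over cco-1 goes from 3111 to 27918 counts for H3K18ac and from 10146 to 32055 for H3K27ac.

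Among regulators of the UPRmt, H3K18ac rose 1.96-fold (1.82 to 2.11) at the strongest peak assigned to atfs-1, the transcription factor that activates the response, which lies downstream of the gene (chromosome V, 14198838 to 14200643). The peak over the start of atfs-1 (14192684 to 14194183) had a fold of 1.06 (0.964 to 1.17), and one just inside the gene (14194402 to 14195205) rose 1.66-fold (1.52 to 1.81). Weaker upstream peaks had folds of 0.63 (0.48 to 0.83, at 14191741 to 14191952) and 0.97 (0.79 to 1.18, at 14192300 to 14192624). H3K18ac rose inside dve-1 (log2 ratio 0.64), which encodes a homeodomain factor of the response, and at cbp-1, the worm CREB-binding protein homologue, the stronger peak had a fold of 0.96 (0.88 to 1.05) and the other, also inside the gene (chromosome III, 9767983 to 9768380, 746 to 613 counts), 0.76 (0.68 to 0.85). After cco-1, the largest rises among genes with peaks of at least median strength were at the homeobox gene ceh-93 (3.24-fold), the epoxide hydrolase gene ceeh-1 (2.71-fold), Y37D8A.8 (2.55-fold), the bZIP factor gene zip-12 (2.48-fold), the nuclear receptor gene nhr-132 (2.47-fold), the thiolase gene acaa-2 (2.46-fold), mef-2 (2.41-fold), mrp-8 (2.40-fold) and R05C11.4 (2.37-fold). The largest falls under the same limit were at catp-7 (log2 ratio -1.95), H05O09.3 (-1.95), the ribosomal RNA gene rrn-2.1 (-1.82), Y59H11AM.1 (-1.79), B0403.6 (-1.68), the F-box gene fbxb-62 (-1.58), Y24F12A.4 (-1.42), C16C8.10 (-1.40), the lectin gene clec-113 (-1.40) and Y5F2A.3 (-1.40). The peak assigned to catp-7 lay 3603 bp from its start, and the peak nearest to that start had a log2 ratio of 0.47. Other falls also lay far from the assigned start: H05O09.3 (19584 bp), Y59H11AM.1 (5548 bp), C16C8.10 (2935 bp) and B0403.6 (2079 bp). So did the rises at Y37D8A.8 (3189 bp), zip-12 (2453 bp) and R05C11.4 (2441 bp, inside the gene).

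UPRmt effector genes, mainly mitochondrial chaperones, proteases and import factors, carried more H3K18ac as a group. Of 13 measured members 9 rose, 0 fell and 4 stayed within 1.5-fold, with a median log2 ratio of 0.71. The list also holds genes of other functions, such as skn-1, gpd-2 and the lectin gene clec-17; the 8 chaperone, protease and import genes alone, a subset chosen after the data were seen, had a median of 0.74 (6 higher, 0 lower, percentile 100). Members that rose included hsp-60 (0.90), the stress regulator skn-1 (0.85), the import receptor gene tomm-20 (0.83) and the protease gene ymel-1 (0.77). For hsp-6 the list used the stronger peak, over the gene start, with a log2 ratio of -0.06, while weaker peaks within the gene had 0.90 and 0.67. Glycolysis and gluconeogenesis genes had a median of 0.51, with 7 of 18 higher and 0 lower, among them enol-1 (0.84), hxk-1 (0.78), pyk-1 (0.77) and aldo-2 (0.75). The cytosolic ribosome genes had a median of 0.29, with 2 of 54 higher and 0 lower (rps-28, 0.79, and rpl-37, 0.69). The autophagy and lysosome genes had a median of 0.18, with 3 of 34 higher and 0 lower, among them epg-9 (0.66) and vha-1 (0.64). These 4 medians lay at percentiles 100, 100, 99.96 and 98.05 of random lists matched on peak strength.

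H3K18ac was lower at cuticle collagen genes, with a median log2 ratio of -0.29, where 18 of 111 fell and 2 rose. Those that fell included col-66 (-0.97), col-163 (-0.87) and col-108 (-0.80), while col-120 rose (0.84). Histone genes taken by symbol had a median of -0.43, with 7 of 15 lower, 0 higher and 8 within 1.5-fold, among those lower his-32 (-1.04), his-68 (-0.96) and his-2 (-0.89). The hypodermis markers had a median of -0.51, with 3 of 6 lower: elt-1 (-0.77), bli-1 (-0.69) and dpy-7 (-0.61). In all, 5 genes belong to 2 lists each: bli-1, col-19, dpy-7 and rol-6, which make up 4 of the 6 hypodermis markers and are also counted among the collagens, and gpd-2, counted among the UPRmt effectors and the glycolysis genes. These medians lay at percentiles 0.00, 0.19 and 1.11 of matched random lists. Near-identical copies within the histone, collagen and ribosomal gene families may share reads, so values of single members are uncertain.

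The other lists lay inside the range of matched random lists for H3K18ac. Oxidative phosphorylation genes had a median of 0.22 (3 of 18 higher, 0 lower), with rises at atp-2 (0.65) and cco-2 (0.61) besides cco-1, and a median of 0.21 without cco-1. The mitochondrial ribosome had a median of 0.14 (2 of 33 higher, 1 lower), the tricarboxylic acid cycle 0.39 (0 of 6 past 1.5-fold) and the UPRmt transcription and chromatin regulators 0.15 (2 of 8 higher, 2 lower). Cytosolic heat shock genes had a median of 0.30 (2 of 5 higher, 1 lower), the endoplasmic reticulum unfolded protein response 0.22 (1 of 9 higher, 0 lower), oxidative stress and detoxification 0.13 (2 of 12 higher, 0 lower) and innate immunity 0.42 (0 of 5 past 1.5-fold). Among tissue markers, the median was -0.23 for germline and oocyte (1 of 8 lower, glh-2 at -0.59), -0.49 for sperm (2 of 7 lower), -0.27 for body wall muscle (1 of 7 lower, unc-54 at -0.68), 0.09 for intestine (0 of 7 past 1.5-fold) and 0.10 for neuron (3 of 11 higher, among them snb-1 at 0.85). The only measured pharynx gene, ceh-34, fell (-0.61).

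By size, 1577 H3K18ac peaks (9.16%) were at least 1.5-fold higher and 2264 (13.2%) at least 1.5-fold lower with cco-1 RNAi, corresponding to 956 and 1560 genes. Counts without scaling to the library total gave 2425 higher and 1569 lower, and the pseudocount planned before the data were examined gave 831 and 1171.

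The same comparison for H3K27ac asked where this mark changed. H3K27ac rose at cco-1, where the peak (chromosome I, 9785901 to 9789947) went from 10146 to 32055 counts, 3.15-fold (3.08 to 3.22). It rose 1.65-fold (1.61 to 1.68) at hsp-60. At hsp-6 the only H3K27ac peak over the gene (chromosome V, 4825186 to 4827769) was assigned by the authors to C37H5.5, and it went from 5010 to 6579 counts, a fold of 1.31 (1.26 to 1.36). The stronger peak inside dve-1 had a log2 ratio of 0.49, and a weaker one 0.26. The folds were 1.38 (1.30 to 1.45) over the start of atfs-1 and, at the 2 peaks inside cbp-1, 0.96 (0.89 to 1.04) and 1.06 (0.969 to 1.17), and a weaker peak downstream of atfs-1 (14198917 to 14199289) rose 1.82-fold (1.62 to 2.04).

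Among genes with peaks of at least median strength, the largest H3K27ac rises were at ceh-93 (4.75-fold, 4.26 to 5.32), M02F4.11 (4.29-fold), DC2.5 (4.14-fold), C04E7.4 (3.85-fold), the solute carrier gene slc-17.4 (3.66-fold), ZK1128.10 (3.18-fold), cco-1, F09E10.1 (3.09-fold), ceeh-1 (3.07-fold) and H28G03.1 (3.05-fold). The peaks used for C04E7.4 and H28G03.1 lay upstream, and the peak nearest to each gene start had a log2 ratio of -0.068 and -0.59. The largest falls under the same limit were at F40G9.6 (7.19-fold lower), Y82E9BR.1 (5.30-fold), F44F1.6 (4.42-fold), R07C3.3 (4.29-fold), C40A11.6 (4.09-fold), Y71F9AL.6 (4.01-fold), C40A11.4 (3.97-fold), T02G5.4 (3.96-fold), T26C12.8 (3.89-fold) and the piRNA locus 21ur-973 (3.67-fold).

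UPRmt effector genes had a median H3K27ac log2 ratio of 0.75, with 7 of 10 higher, 0 lower and 3 within 1.5-fold. The 6 chaperone, protease and import genes alone had a median of 0.90 (5 higher, 0 lower, percentile 100). Of the 23 listed effector genes, 13 were measured for H3K18ac and 10 for H3K27ac. For H3K27ac hsp-6 is not among them, because its peak, with a fold of 1.31, was assigned to C37H5.5. The highest were dnj-10 (1.26), the protease genes spg-7 (1.14) and ymel-1 (1.01), and gpd-2 (0.86). Glycolysis and gluconeogenesis genes had a median of 0.43, with 6 of 18 higher and 0 lower, among them aldo-1 (1.22), hxk-1 (1.12), ipgm-1 (1.08) and pyk-1 (1.06). The peak used for pyk-1 lay inside the gene, and the one nearest to its start had a log2 ratio of -0.45. Autophagy and lysosome genes had a median of 0.23 (6 of 35 higher, 0 lower), with atg-3 at 0.99 and unc-51 at 0.84, although the peak nearest to the start of unc-51 had -0.27. The mitochondrial ribosome had a median of 0.07 (5 of 39 higher, 1 lower), with mrpl-38 at 1.17. The medians of these 4 lists lay at percentiles 100, 99.96, 99.81 and 98.07 of matched random lists, and relative to all H3K27ac peaks, whose median was -0.19, they were 0.95, 0.62, 0.42 and 0.26. Oxidative phosphorylation genes had a median of 0.30 (5 of 18 higher, 0 lower), among them cco-2 (0.91), asg-2 (0.90) and asb-2 (0.89), at percentile 98.65. Without cco-1, the RNAi target, the median was 0.23 (4 of 17 higher, 0 lower), at percentile 94.93, inside the range of random lists. A median does not weigh the size of the cco-1 rise, so this change shows only that the position hung on a single member above the median.

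H3K27ac was lower at histone genes, with a median log2 ratio of -1.05, where 14 of 20 fell and 0 rose, among them his-7 (-1.71), his-31 (-1.57) and his-1 (-1.47). Germline and oocyte markers had a median of -0.56, with 5 of 12 lower and 0 higher, among them mex-5 (-0.97), puf-5 (-0.91) and oma-2 (-0.86). Sperm markers had a median of -0.79 (5 of 9 lower), and hypodermis markers -0.51 (2 of 6 lower, elt-1 at -0.77 and dpy-7 at -0.65). Cuticle collagen genes had a median of -0.16, with 17 of 116 lower and 2 higher, but the median was 0.028 relative to all peaks and 0.011 with TMM scaling, so no direction is given for the group. These medians lay at percentiles 0.00, 0.11, 1.73, 1.27 and 0.59 of matched random lists. Relative to all H3K27ac peaks the histone, germline, sperm and hypodermis medians were -0.86, -0.37, -0.60 and -0.32, with 14, 4, 5 and 0 genes past 1.5-fold lower.

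**Figure D2:**
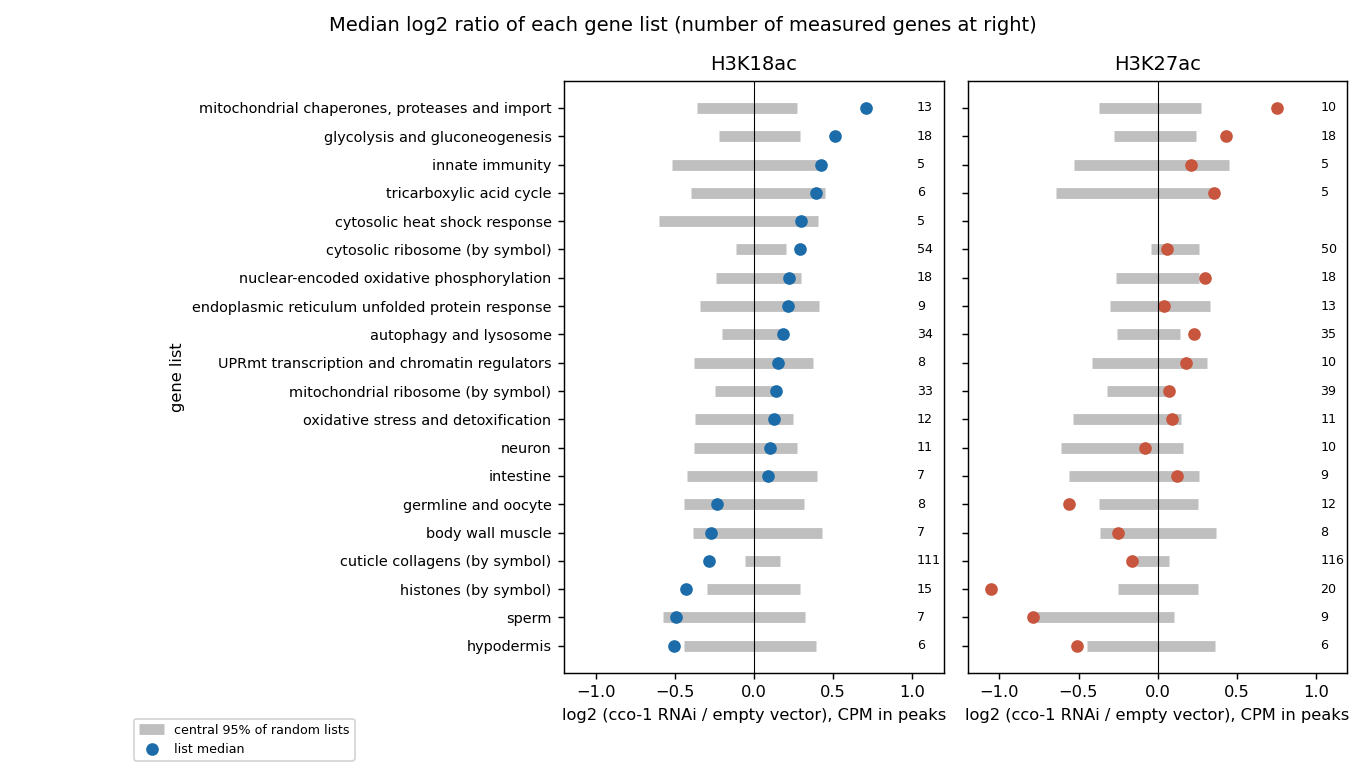
Median log2 ratio of each gene list (points) for H3K18ac and H3K27ac, with grey bars for the central 95% of random lists of the same size matched on peak strength and the number of measured genes at the right of each panel. Lists with at least 5 measured genes are drawn; the list of mitochondrial chaperones, proteases and import (UPRmt effectors) has medians of 0.71 and 0.75, and histone genes -0.43 and -1.05.

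The other lists lay inside the range of random lists for H3K27ac. The median was 0.06 for the cytosolic ribosome (5 of 50 higher, 0 lower), 0.35 for the tricarboxylic acid cycle (0 of 5 past 1.5-fold), 0.18 for UPRmt transcription and chromatin regulators (2 of 10 higher, 3 lower), 0.04 for the endoplasmic reticulum unfolded protein response (1 of 13 higher, 1 lower), 0.09 for oxidative stress and detoxification (2 of 11 higher, among them gcs-1 at 1.26 and trx-2 at 1.02) and 0.21 for innate immunity (1 of 5 lower). The gene that fell in the last list was irg-3 (-0.69), whose peak nearest to the start had 0.18. Intestine markers had a median of 0.12 (1 of 9 higher, act-5 at 1.13, and 2 lower), body wall muscle -0.25 (1 of 8 lower, hlh-1 at -1.07) and neuron -0.08 (1 of 10 higher, snb-1 at 0.62, and 2 lower). With fewer than 5 measured genes, cytosolic heat shock genes had a median of -0.01 (0 of 4 past 1.5-fold), and pharynx markers -0.99 (2 of 3 lower).

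By size, 1551 H3K27ac peaks (8.73%) were at least 1.5-fold higher and 4098 (23.1%) at least 1.5-fold lower, corresponding to 1094 and 2744 genes. This split depended on the scaling and on weak peaks: it was 2621 higher and 2564 lower with median scaling, 2507 and 2685 with TMM scaling, 2228 and 1768 after centring on peak strength, 806 and 997 among peaks of at least median strength, and 1017 and 2055 with the pseudocount planned before the data were examined. The median log2 ratio went from -0.65 in the weakest decile of H3K27ac peaks to 0.12 in the strongest, and from -0.15 to 0.14 for H3K18ac.

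**Figure D3:**
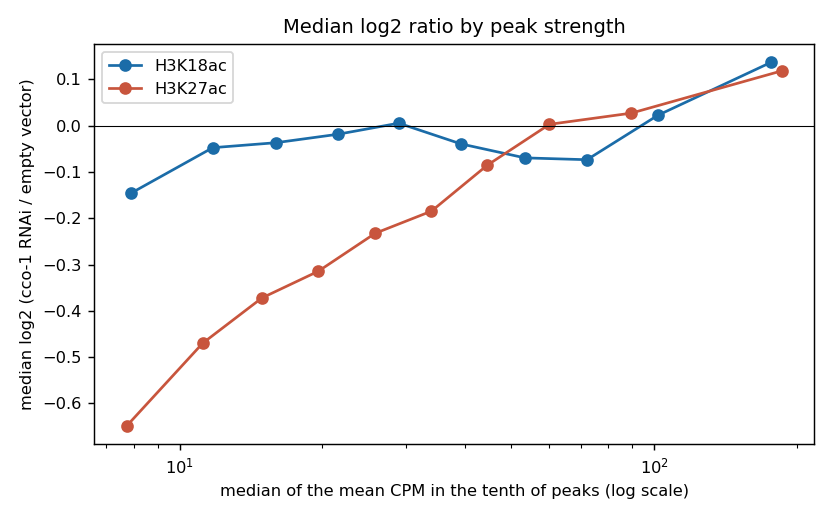
Median log2 ratio of cco-1 RNAi over empty vector against the median CPM of each decile of peaks by strength (log scale), for both marks. The H3K27ac median goes from -0.65 in the weakest decile to 0.12 in the strongest.

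The 2 marks were then compared gene by gene, to ask whether they changed at the same genes. Across the 10058 genes with a peak for both, the log2 ratios had a Pearson r of 0.59 and a Spearman rho of 0.58, and 70.6% had the same sign. Both marks were at least 1.5-fold higher at 286 genes, against 69.9 for independent lists, and at least 1.5-fold lower at 643, against 222. The balance of shared rises and falls depended on the scaling: 469 genes were higher and 415 lower in both marks with median scaling, and 448 and 443 with TMM scaling. Of the 10 genes with the largest rise, 3 were shared by the marks (cco-1, ceh-93 and ceeh-1), and of the 10 with the largest fall 0 were shared. Among the UPRmt effector genes measured for both marks, 9 of 10 had a positive log2 ratio in both, as did 14 of 18 glycolysis genes. Of the germline markers 6 of 7 were negative in both, and of the hypodermis markers 6 of 6. Histone genes lie close together, so the same place was often assigned to different symbols: matched by symbol, 4 of 7 were negative in both and 2 positive in both, with medians of -0.032 for H3K18ac and -0.82 for H3K27ac. Matched by overlapping peaks, which was chosen after the data were seen, 11 of 14 pairs were negative in both and 2 positive in both, and 7 fell at least 1.5-fold in both.

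Opposite changes of at least 1.5-fold were rare: 7 genes were higher in H3K18ac and lower in H3K27ac, and 4 genes, named after their values were seen, were lower in H3K18ac and higher in H3K27ac (nhr-122, Y54E5B.6, ubl-5 and marb-1). Of these 11 genes 6 compare overlapping peaks, which leaves out nhr-122, and 0 genes moved in opposite directions among those with peaks of at least median strength in both marks. The split of 7 and 4 depended on the scaling: it was 5 and 11 with median scaling, 5 and 10 with TMM scaling, 5 and 12 after centring on peak strength, and 19 and 2 without scaling. The largest H3K18ac fall, at catp-7, had an H3K27ac log2 ratio of -0.08, and B0403.6 had 0.06, whereas rrn-2.1 fell in both (-1.82 and -1.75). Genes are not independent replicates, and libraries of the 2 marks may come from the same worms, so part of the shared pattern may belong to the samples.

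**Figure D4:**
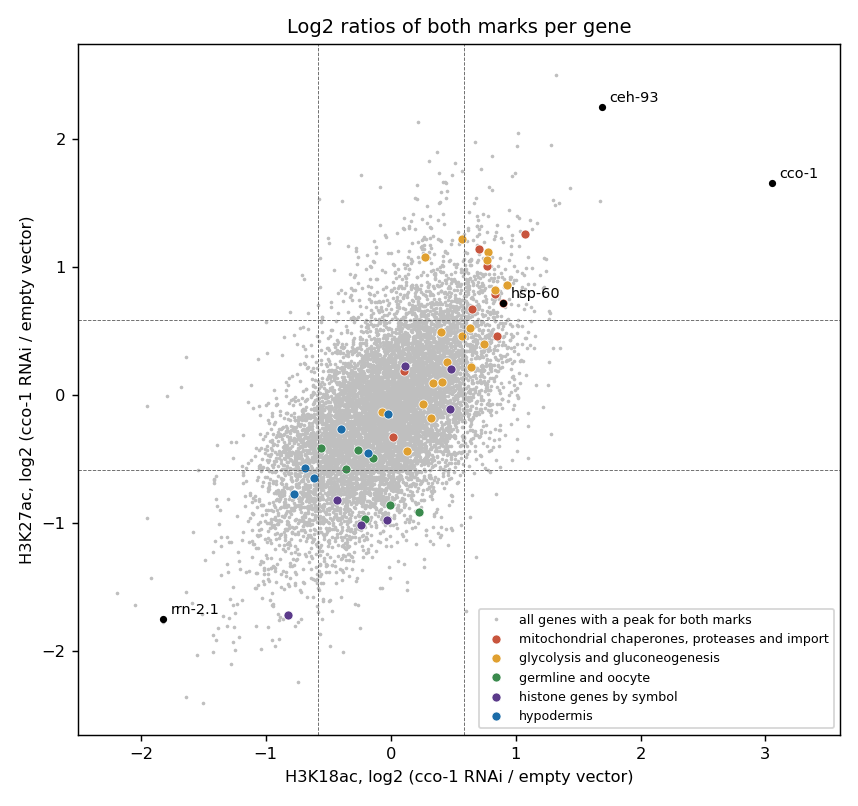
Log2 ratio of cco-1 RNAi over empty vector for H3K18ac (horizontal) and H3K27ac (vertical) at each of the 10058 genes with a peak for both marks, with members of 5 lists coloured and dashed lines at 1.5-fold. Across genes Pearson r is 0.59.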

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

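The search for list genes that moved in opposite directions in the 2 marks was chosen after the data had been seen. It found ubl-5, a ubiquitin-like factor of the mitochondrial unfolded protein response, with a log2 ratio of -0.69 in H3K18ac (108 to 72 counts, chromosome I, 5608643 to 5609283) and 0.91 in H3K27ac (58 to 109 counts, 5608455 to 5608843). The difference between the marks was not tested, and the counts are low.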

How the results depend on the processing

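Unscaled counts, TMM scaling, centring on peak strength and cutting members from lists were chosen after the data had been seen. Over all alternatives, 1581 values of named genes kept their side of 1.5-fold, 101 dropped under it and 38 passed it. Another 10, of genes past 1.5-fold in the leading values, changed sign. Turns near 0 count as kept: H3K18ac at hsp-6 had a fold of 0.96, but unscaled counts of 2391 and 2477. With peaks of at least median strength all 195 values stayed the same by construction, because named genes were chosen above that limit. Genes named under several rules count more than once. Of the list medians 279 moved by less than 1 SD of random lists, 60 moved more and 2, both of the H3K27ac collagens, were counted as a change of sign. These 2 do not cover every change of sign. The H3K27ac neuron median went from -0.08 to 0.11 with median scaling and was counted by the size of its move. Depth limits weak peaks, and peak choice limits genes with several peaks; beyond the construction of each alternative, the cause was not tested. No paired analysis was possible because each group has 1 library. A stricter peak threshold was not run.

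The counts of peaks higher and lower, in that order, were 194 and 459 (H3K18ac) and 468 and 1317 (H3K27ac) at 2-fold; 791 and 929, and 806 and 997, among peaks of at least median strength; 831 and 1171, and 1017 and 2055, with a pseudocount at the 5th percentile; and 200 and 174, and 326 and 319, with 5 times that pseudocount. Unscaled counts gave 2425 higher H3K18ac peaks. For H3K27ac, median scaling gave 2621 and 2564, TMM scaling 2507 and 2685, and centring on peak strength 1768 lower peaks.

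The correlation of the marks was 0.67 and the share with the same sign 74.6% at median strength or above for both; that share was 71.7% after centring and 67.5% without scaling. With overlap of at least 50% of each peak, 73.8% of H3K18ac and 74.4% of H3K27ac peaks overlapped. Within 500 bp of a start lay 49.5% and 50.0%.

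The H3K27ac collagen median turned to 0.028 with median scaling and 0.011 with TMM scaling. With the peak nearest to the gene start, log2 ratios turned to 0.47 for catp-7 (H3K18ac) and, for H3K27ac, -0.068 for C04E7.4, -0.59 for H28G03.1, -0.45 for pyk-1, 0.18 for irg-3 and -0.27 for unc-51. With peaks within 1 kb of the start, they were -0.62 for C04E7.4, -0.59 for H28G03.1, -0.45 for pyk-1 and 0.18 for irg-3.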

Other observations

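Grouping genes by symbol, the tests of the cco-1 and rDNA patterns, and the comparisons of hypodermis and of chromosome X were chosen after the results were seen; centring on peak strength was added after the data had been seen, with its bounds set before its result. Acetylation was lower at some gene families and not at others. Among 71 families with at least 10 measured genes, the F-box families fbxb and fbxc had H3K18ac medians (log2) of -0.95 (25 of 33 lower, 0 higher) and -0.84 (13 of 15 lower), and H3K27ac medians of -1.26 (34 of 45 lower) and -1.38 (14 of 19 lower, 1 higher). The largest F-box family, fbxa, showed no such shift, with medians of -0.06 (16 of 68 lower, 5 higher, percentile 35) and -0.28 (17 of 69 lower, 8 higher, percentile 37.2). The MATH-domain genes math had medians of -0.59 and -0.63, the chemoreceptor families srh -0.37 and -0.62, sri -0.66 and -0.58 and srw -0.59 and -0.48, and the C-type lectins clec -0.42 (35 of 95 lower) and -0.52 (42 of 99 lower), for H3K18ac and H3K27ac. Of the other chemoreceptor families, srt was below random lists in both marks (percentiles 0.9 and 2.3), and srx, srz, str and srg were below them in H3K18ac (0, 0, 0.2 and 1) and inside their range in H3K27ac (5.4, 9.2, 4.7 and 5.8). The families sre (percentiles 4 and 3.9) and srbc (44.6 and 51.8, medians -0.05 and -0.14) were inside the range in both marks, and differences between families were not tested. Nuclear receptor genes of the nhr family had medians of 0.12 (18 of 110 higher, 13 lower) and 0.07 (32 of 109 higher, 16 lower). The median of all H3K27ac peaks was -0.19. Of the families given here, fbxb, fbxc, math, srh, sri, srw, clec and nhr kept the sign of their medians with median scaling, TMM scaling, unscaled counts and centring on peak strength, but centring changed the size of the H3K27ac medians, to -0.76 for fbxb, -0.91 for fbxc, -0.45 for math, -0.29 for srh, -0.46 for sri, -0.28 for srw, -0.26 for clec and 0.27 for nhr. Copies of these genes resemble each other and lie in clusters, so their peaks are not independent.

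The share of lower peaks differed between chromosomes. On chromosome II 16.8% of H3K18ac and 28.3% of H3K27ac peaks were at least 1.5-fold lower, against 8.68% and 16.9% on chromosome III. The H3K18ac falls at Y59H11AM.1 and catp-7 lie next to each other on chromosome IV (8576986 to 8577366 and 8580667 to 8581939), with H3K27ac log2 ratios of -0.00 and -0.08.

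Both marks rose at the RNAi target, with gains of 2745 CPM for H3K18ac and 1887 CPM for H3K27ac. Among the other oxidative phosphorylation genes the largest H3K27ac log2 ratio was 0.91, at cco-2, below the 1.66 of cco-1. These H3K27ac values, and the place of cco-1 as the largest H3K18ac rise of all, were known before the comparison was chosen. The comparison is therefore no separate test of a rise of these genes as a group. A group rise smaller than that of cco-1 is not denied. The 17 other genes had medians 0.24 (H3K18ac) and 0.42 (H3K27ac) above that of all peaks, with 2 and 4 higher and 0 lower, inside the range of random lists. The other peaks within 20 kb reached at most 0.60, which bounds the gain closely in H3K18ac only, since the risen H3K27ac peak extends beyond the gene and has no other peak near it. DNA of the cco-1 feeding plasmid, carried over with the bacteria, may be its source. The inputs and the ends of the plasmid insert were not analysed here, so a gain of acetylation at the gene itself stays open.

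The peak over the repeated ribosomal RNA genes at rrn-2.1 (chromosome I, 15064121 to 15067536) fell from 1.12% to 0.316% of H3K18ac counts in peaks, and in H3K27ac from 0.888% to 0.264%. Relative to the library total, strong peaks did not share this fall. The 10% of peaks with most empty-vector counts had a median log2 ratio of -0.025 in H3K18ac and 0.007 in H3K27ac. Values are scaled to the total in the same peaks, which limits how far such a median can move. A general fall of strong peaks is therefore not excluded. A test on the 10 other peaks with most counts, run earlier, gave -0.55 in H3K18ac and -0.046 in H3K27ac. It leaves a general fall open for the few highest peaks of H3K18ac. The log2 ratios of the marks at this rDNA peak differed by -0.070, which a change of rDNA or background DNA that does not depend on the antibody could give. Weaker rRNA gene peaks on chromosome V also fell, with less even agreement. H3K18ac and H3K27ac had -1.04 and -1.04 at rrn-4.11, but -0.24 and -0.65 at rrn-4.6. At rrn-4.15 the H3K18ac peaks had -0.51, -1.03 and -0.97, and the H3K27ac peak had -0.65. Without the inputs, and with reads shared among repeat copies, a loss of both marks from the rDNA may equally be the source and was not tested.

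Acetylation was lower than at matched random lists at histone and hypodermis genes in both marks, at germline genes in H3K27ac (in H3K18ac their median of -0.23 was inside the range, and the difference between marks was not tested), at sperm genes in H3K27ac (-0.79, and -0.49 in H3K18ac, inside the range), and at collagen genes, without a direction that held under all scalings in H3K27ac. A shift of weak against strong peaks is argued against as the whole cause for histone genes. Their weaker median after centring was -0.49, below random lists in both marks. The weaker collagen median was -0.15, also below random lists in both marks. The col genes alone, without centring, had an H3K27ac median of -0.11 at percentile 7.9, inside the range, and -0.29 at percentile 0 in H3K18ac. Such a shift as the whole cause is therefore argued against for collagens in H3K18ac only. The random lists were already matched on peak strength, so centring is not separate evidence. For germline genes the centred median was -0.56 in H3K27ac, below random lists, so centring did not remove that fall. In H3K18ac the germline list was inside the range before centring and after it (-0.21). The bound set beforehand, which asked for both marks, was not met, so the question stays open for germline genes. A lower share of germline nuclei would raise somatic genes, so alone it would not lower the hypodermis list. The median of that list lay 0.48 (H3K18ac) and 0.32 (H3K27ac, -0.32) below that of all peaks, with 5 of 6 genes below it in each mark. The list was known to be low before this comparison was chosen, so the comparison is no separate test. Other somatic lists went both ways. Relative to all peaks, intestine had 0.11 and 0.31, neuron 0.13 and 0.11, and body wall muscle -0.24 and -0.05, for H3K18ac and H3K27ac. A lower germline share in the worms therefore stays open. For germline genes themselves it cannot be told apart. X minus autosomes was 0.081 for H3K18ac and -0.054 for H3K27ac. These values cover unlike parts of X, to 7.89 Mb for H3K18ac and 12.9 Mb for H3K27ac. They are also not matched on peak strength, so the difference in sign between the marks decides nothing. A difference in developmental stage between the worms, or a response of these genes to mitochondrial stress, may also contribute, and neither was tested.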
